A study of Arabidopsis thaliana with 11 samples.

How the data were processed

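Transcript levels were measured in enriched guard cell fractions of Arabidopsis thaliana with single-colour Agilent arrays, 11 in all. The genotype labels give 4 lines: ost1-2 (2 arrays), ler, the Landsberg erecta line (3), slac1 (3) and gl1-1 (3). OST1 is a kinase of abscisic acid (ABA) signalling, and SLAC1 is the main anion channel of guard cells. The series' design text pairs ost1-2 with ler and slac1 with gl1-1, and calls the replicates biologically independent. The labels name the slac1 allele in 2 ways, as slac1-3 in the source name and as slac15 or slac1-5 elsewhere, so the line is called slac1 here. Per the labels' protocols, plants grew in soil with 8 h of light and 16 h of darkness at 22 and 16 °C under 100 µmol m-2 s-1 of white light, and were sampled after 5 h of light.

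Per the file headers, the authors' deposited spot intensities came from Agilent Feature Extraction 9.5.3.1. The processed signal is a linear intensity after subtraction of a spatially fitted background, a multiplicative correction across the array and replacement of very dim values by surrogates, with no scaling between arrays. The mean signal and the local background, also deposited intensities, are raw scanner values. The series' value table was compared with the scanner values array by array. Its order of spots was that of the log2 mean signal (Spearman correlation of 1, and of 0.994 and 0.995 for gl1-1 replicates 1 and 2). The median of the deposited log2 values was 8.28 on every array and the quartiles were 7.01 and 10.3, as quantile normalisation without background subtraction gives. The tool behind it is not given in the sources used here.

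Each array held 45220 spots, of which 1417 were controls. Spots marked as non-uniform or as population outliers were left out (11 to 47 per array), no spot was saturated, and spots of 1 probe were averaged. Of 43603 probes, 38184 named 1 gene locus, 873 named several and 4546 named none. Probes without a single locus stayed out of gene counts. Symbols came from the RefSeq table of the TAIR10.1 assembly, in which 23743 of the 24027 loci tested were found and 284 were not. That table was also used to say which genes neighbour each other.

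The values tested were log2 processed signals minus each array's 75th percentile over non-control spots. A probe was tested if it was well above background on every array of at least 1 group (36564 probes). A gene was represented by its tested probe with the highest mean over all arrays, which gave 24027 genes, 6525 of them with over 1 tested probe. A linear model was fitted with limma 3.58.1 in R 4.3.3 (files were read with the data.table package, version 1.17.8), with lmFit and eBayes over all 11 arrays, 4 group means, 7 residual degrees of freedom and 1.47 prior degrees of freedom. Contrasts were ost1-2 minus ler, slac1 minus gl1-1, the difference between these, and gl1-1 minus ler. Every adjusted p for a gene is limma's with Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The number of arrays limits the precision. In the ost1-2 group, with 2 arrays, the test borrows its spread from the other lines.

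For genes not well above background on any array of a group, the fold is a lower bound, written as at least N-fold. It sets the mean of the brighter group against the mean, per array, of the higher of the dim probe's own value and the lowest signal among probes well above background.

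Lists of 19 gene groups, 415 loci with 395 tested, were fixed by locus. They were guard cell ion transport; ABA synthesis, breakdown and transport; ABA receptors, phosphatases, kinases and factors; CO2, calcium, redox and light signalling in guard cells; ABA-induced genes; guard cell identity; stomatal lineage. Markers of other cells were photosynthesis (mesophyll-rich), trichome, epidermis and cuticle, and vasculature. Signs of handling were jasmonate and wounding, touch and rapid stress, and heat shock, and the others were salicylate and immunity, circadian clock, flavonoid and anthocyanin, glucosinolate, and starch and malate metabolism. Some loci stand in several lists. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 19 lists of a contrast. All list calls of the main fit were also tested with a correlation estimated for each list. For members, the count past the threshold over all genes is given beside the count adjusted over the list alone. The median log2 change over all genes was -0.09 in ost1-2 against ler and -0.08 in slac1 against gl1-1. It was -0.02 in the difference and 0.06 in gl1-1 against ler. Camera sets a list against the other genes, so list medians and counts above 0 are to be read beside these values.

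The genes named were set by rule: OST1, SLAC1 and GL1; the 8 highest and 8 lowest fold changes per comparison among genes past the threshold whose arrays did not overlap between groups; and up to 4 members per list past the threshold by adjusted p, or, for a list with none, up to 2 with the largest change, given as values. Not every gene the rule allows is printed. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. Calls common to both mutants are given beside n1 × n2 / N, the count for independent lists. The planned Fisher's exact test (two-sided) was run, and its p is not printed because the lists are not independent: the mutant comparisons share no array but share each gene's spread and slide 1.

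The alternatives were normexp background correction (offset 50) with quantile normalisation, quantile normalisation alone, median centring, the authors' values, no filter and a stricter filter on dim probes, other probe rules, a fit to the 2 groups alone, a replicate block, trended and robust eBayes, array weights, slide as a block, each array left out in turn, and a 2-fold threshold. A lone array left in ost1-2 was then assumed to vary like the other groups. Slide (5 slides) and scan day (4 days) came from the file headers and are numbered here. Added after the data were examined were fits without slide 1, with scan day as a block, and over the brighter genes, those above the median of mean signal.

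The steps were tested on simulated data with the real means and spreads. Noise was drawn independently for each gene and array, without correlation between genes and without slide effects. The simulation therefore does not show how such features of the real data affect gene or list calls. In the simulated ost1-2 against ler comparison of 24027 genes, 50.7, 68.7 and 89.4% of the genes changed by 1, 2 and 3 log2 units were recovered, with 6 unchanged genes called. In the simulated slac1 against gl1-1 comparison of 24027 genes the shares were 49.3, 76.1 and 89.4%, with 9 unchanged genes called. A shift of 0.5 log2 units put into the ABA-induced list gave an adjusted p of 2.2e-11, and no unshifted list was called.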

Results

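The data were 11 arrays of RNA from leaf fractions enriched in guard cells, the paired cells that open and close the stomatal pore. Lines carrying mutations in OST1 (2 arrays) or SLAC1 (3 arrays) were each set against a control line, ler (3 arrays) or gl1-1 (3 arrays). The share of non-control spots well above background was 74.1 and 74.3% in the ost1-2 arrays, 83.0, 81.5 and 83.5% in ler, 75.9, 68.2 and 93.8% in slac1 replicates 1 to 3, and 83.0, 91.2 and 84.3% in gl1-1. The first principal component of the 24027 genes tested held 55.4% of the variance and the second 26.4%. On the first component slac1 replicate 3 scored 108.8, near the gl1-1 arrays at 100.5, 110.5 and 69.8. There slac1 replicates 1 and 2 scored 5.99 and 12.2. On the second component slac1 replicates 1 and 2 scored 96.7 and 114 and slac1 replicate 3 scored -42.1, near gl1-1 replicate 2 at -40.5. Slide 1, whose header gave no spike-in signal, held ost1-2 replicate 1 and slac1 replicate 2. Slide 2 held ost1-2 replicate 2 and all 3 ler arrays, slide 3 the other slac1 arrays, slide 4 gl1-1 replicates 1 and 2, and slide 5 gl1-1 replicate 3.

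The mutated genes were examined first. SLAC1 transcript was 11.2-fold lower in slac1 than in gl1-1, at -2.80 ± 0.61 against 0.69 ± 0.17 (log2 signal relative to the array's 75th percentile, SD, n = 3 each; limma log2 change -3.49, SE 0.26, adjusted p = 0.00563). It was low in all 3 slac1 arrays, though still well above background. In slac1 against gl1-1, the SLAC1 call was lost with only the arrays of the 2 groups compared (limma adjusted p = 0.207). It was also lost with replicate number as a replicate block (limma adjusted p = 0.0954). The log2 change was -3.49 in both of these fits. SLAC1 did not pass the test in ost1-2 against ler (log2 change 0.22, SE 0.29, limma adjusted p = 0.721). OST1 transcript was well above background in every array. Its log2 change was 0.74 in ost1-2 (SE 0.16, limma adjusted p = 0.087) and 0.82 in slac1 (SE 0.14, limma adjusted p = 0.0624), neither past the threshold, so the array gives no check of the ost1-2 label. These values are from the brightest of 3 probes, and the others gave 0.71 and 0.06 in ost1-2 and 1.38 and 0.71 in slac1. GL1, the trichome regulator named by the gl1-1 line, had a single probe, well above background only on 1 ost1-2 array, and was not tested.

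**Figure D1:**
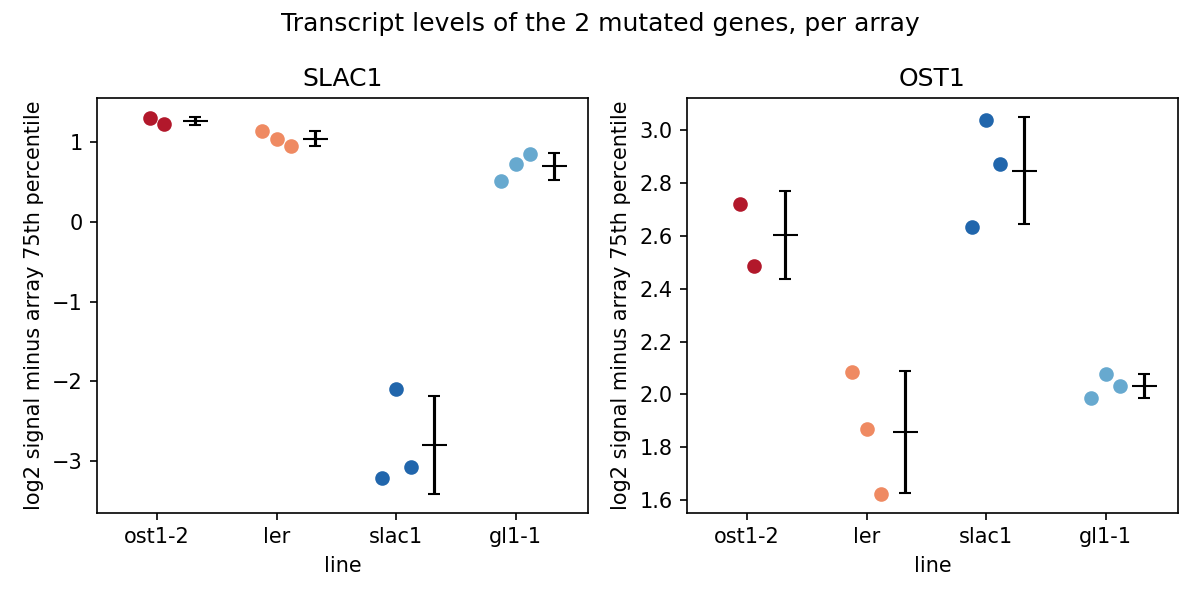
Log2 signal minus the array's 75th percentile for the brightest probe of SLAC1 (left) and OST1 (right) in each line. Points are arrays, and black marks are the group mean with its SD (n = 2 for ost1-2, 3 elsewhere). SLAC1 lies at -2.80 on average in slac1 and between 0.69 and 1.26 in the other lines.

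The comparison of ost1-2 with ler asks which transcripts differ in guard cells without a working OST1 kinase. Of the 8 genes that rose most, 3 (LEA7, LEA4-5 and RD29B) stand in the fixed ABA-induced list. AT3G17520, a late embryogenesis abundant (LEA) protein gene, was 94.0-fold higher (log2 change 6.55, SE 0.70, limma adjusted p = 0.00772), LEA7 was 70.3-fold higher (6.14, SE 0.50, adjusted p = 0.00241) and LEA4-5 was 20.9-fold higher (4.38, SE 0.56, adjusted p = 0.018). AT1G72100 rose by 3.53 on the log2 scale, the cytokinin-activating enzyme LOG5 by 3.33, the drought marker RD29B by 2.95 and AT5G07330 by 2.91. AT2G16005 rose by 3.99 and was well above background in 1 of the 3 ler arrays.

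Among the genes lower in ost1-2, MRD1 was 31.1-fold lower (log2 change -4.96, SE 0.26, limma adjusted p = 0.000623) and FER1, a ferritin that stores iron, was 6.91-fold lower (-2.79, SE 0.20, adjusted p = 0.00154). MAF4, a MADS-box gene of the flowering repressor family, was 7.91-fold lower (-2.98, SE 0.27, adjusted p = 0.00333). NAC004 fell by 3.20 and PIPK10, a phosphatidylinositol phosphate kinase measured in 1 ost1-2 array, by 2.63. Not well above background in either ost1-2 array were AT4G06536, at least 19.4-fold lower, LUP5, a triterpene cyclase gene, at least 3.49-fold lower, and AT3G06433, at least 2.51-fold lower. All of these were measured in the 3 ler arrays. The 3 probes of AT4G06536 differed in size, at -4.80, -4.36 and -1.06. LUP5 lost its call in 13 of 25 other settings, NAC004 in 14 of 26, AT3G06433 in 12 of 25 and PIPK10 in 14 of 25. MRD1 and FER1 lost theirs in 0 of 27.

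In all, 168 genes passed the threshold, 85 higher and 83 lower (50.6% higher), and 117 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 3867 genes. The split depended on the scaling: 53.4% were higher with median centring, 66.8% with quantile normalisation, 71.5% with normexp and quantile normalisation, and 74.2% with the authors' values. It also depended on the fit, with 78 higher and 419 lower in a fit to the 2 groups alone and 680 higher and 1365 lower with array weights. Within slide 2, where 1 ost1-2 and 3 ler arrays met, the 168 genes, picked with these same arrays, had a median size of 1.25 log2 units against 1.37 over all arrays. With slide as a fixed block, only MRD1 (-4.41, SE 0.10, limma adjusted p = 0.00128) and FER1 (-3.18, SE 0.14, adjusted p = 0.0201) passed, with 1945 genes at an unadjusted p under 0.05. The count also moved with single arrays. It was 26 without ost1-2 replicate 1, 65 without ost1-2 replicate 2, and 79, 54 and 98 without ler replicates 1, 2 and 3. It was 110 and 568 without slac1 replicates 1 and 3, and 95 and 103 without gl1-1 replicates 2 and 3, which enter the fit through the common spread.

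The ABA-induced list shifted up in ost1-2 (median log2 change 0.20, 24 of 37 measured members above 0, camera adjusted p = 4.19e-06; adjusted p = 0.459 with an estimated correlation). Past the threshold were 5 members, all higher, over all genes, and also 5 adjusted over the list alone. These included LEA7, LEA4-5, RD29B and the transcription factor MYB74 (2.16, SE 0.32). The mean over the list lay at 0.75 and 0.84 in the ost1-2 arrays and at 0.37, 0.06 and -0.17 in ler. Within slide 2 the median was 0.19, and over the brighter genes alone, a setting chosen after the data were examined, the list missed the threshold (adjusted p = 0.0726). The ABA receptor and kinase list did not pass (median 0.00, mean -0.10, adjusted p = 0.175), nor did ABA synthesis, breakdown and transport (median 0.04, adjusted p = 0.353).

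Markers of guard cells moved in the same direction. The guard cell identity list shifted up (median 0.22, 11 of 15 members above 0, camera adjusted p = 0.00066; adjusted p = 0.459 with an estimated correlation), with 0 members past limma's threshold over all genes, 3 adjusted over the list alone and 6 at an unadjusted p under 0.05. The guard cell ion transport list also shifted up (median 0.22, 20 of 29 above 0, camera adjusted p = 1.97e-05; adjusted p = 0.459 with an estimated correlation). It had 0 members past limma's threshold over all genes, 7 adjusted over the list alone, and 9 higher and 2 lower at an unadjusted p under 0.05. The identity and ion transport lists share several loci, among them SLAC1 and ALMT12, so their shifts are not independent. Within slide 2 the medians of these lists were 0.18 and 0.15. The anion channel ALMT12 had a log2 change of 0.78 (SE 0.18, limma adjusted p = 0.103). BLUS1, a kinase of blue light-driven stomatal opening, rose by 1.05 (SE 0.14), the only member past the threshold in its signalling list (median 0.07, camera adjusted p = 0.0679; 3 adjusted over the list alone). With slide as a block that list passed at the preset correlation (median 0.01, camera adjusted p = 0.0423). An estimated correlation, used with the main fit only, gave that list a camera adjusted p of 0.459. Stomatal lineage genes did not pass (median 0.10, adjusted p = 0.71), nor did markers of other cells, with medians of -0.03 for photosynthesis (adjusted p = 0.46), -0.07 for trichome (0.752), 0.04 for epidermis and cuticle (0.134) and 0.13 for vasculature (0.0527). The vasculature list was called up in 9 of the 28 other settings, so the rise was not confined to guard cell markers in these. Epidermis and photosynthesis were called up in 2 each, and stomatal lineage and trichome in 0.

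The salicylate and immunity list shifted down in ost1-2 (median -1.06, 0 of 21 members above 0, camera adjusted p = 2.74e-06; adjusted p = 0.459 with an estimated correlation). It had 0 members past limma's threshold over all genes, 12 adjusted over the list alone, all lower, and 13 at an unadjusted p under 0.05. WRKY38 had a log2 change of -3.89 (SE 0.85, limma adjusted p = 0.0881) and FMO1, an enzyme of systemic resistance, of -3.95 (SE 1.38, adjusted p = 0.233). The ler arrays themselves differed, with list means of -0.13, 1.25 and 0.54, against -1.21 and -0.48 in ost1-2. Within slide 2 the median was -0.79.

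The epidermis list held CER1, of wax alkane synthesis, which rose by 1.55 (SE 0.16), and the cutin enzyme CYP77A6, which fell by 0.67. Among starch and malate genes (median -0.08, camera adjusted p = 0.54), sucrose synthase SUS3 rose by 1.57 and phosphoenolpyruvate carboxylase PPC2 by 0.65, and adjusted over the list alone 4 were higher and 1 lower. The lists for touch (median -0.26, adjusted p = 0.79), jasmonate (-0.05, 0.752), heat shock (0.11, 0.46), clock (-0.05, 0.774), flavonoid (-0.19, 0.711) and glucosinolate genes (0.02, 0.46) did not pass. With slide as a block the jasmonate list was called up (median within slide 2 0.23, camera adjusted p = 0.0467). This call is at the preset correlation, and in the main fit an estimated correlation gave a camera adjusted p of 0.911.

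The comparison of slac1 with gl1-1 asks the same of guard cells with little SLAC1 transcript. Of 113 genes past the threshold, 107 were higher and 6 lower. AT5G24600 was 8.14-fold higher (log2 change 3.03, SE 0.36, limma adjusted p = 0.0193), LOG5 was 5.39-fold higher (2.43, SE 0.32, adjusted p = 0.0245) and MYB74 was 4.86-fold higher (2.28, SE 0.28, adjusted p = 0.0197). CER1 rose by 2.06 (0.75 for its other probe), the borate transporter gene BOR5 by 1.98, and AT2G18969, AT3G48450 and AT3G48970 by 2.19, 2.01 and 1.91. Besides SLAC1, the genes that fell were YUC8, an auxin synthesis enzyme (-1.19, SE 0.16), AT1G29430 (-0.92), PRE1, a growth-promoting regulator (-0.88), AT3G21330 (-0.78) and AT3G09980 (-0.66). YUC8 lost its call in 13 of 26 other settings, AT1G29430 and AT3G21330 each in 18 of 26, PRE1 in 12 of 27 and AT3G09980 in 19 of 27. Among the genes that rose, LOG5 lost its call in 13 of 25, BOR5 in 14 of 27 and AT3G48970 in 3 of 26.

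The count at an unadjusted p under 0.05 was 2918, and 56 of the 113 genes changed at least 2-fold. The count and its direction moved with slac1 replicate 3, whose omission gave 2862 genes, 308 higher and 2554 lower, with all 113 among them. With array weights 1274 were higher and 4731 lower. Without slac1 replicates 1 and 2 the counts were 53 and 15, without each of gl1-1 replicates 1 and 2 it was 5, without each ost1-2 array it was 48, and without ler replicate 2 it was 36. A fit to the 6 arrays of the 2 groups alone called 0 genes by limma, with 1992 at an unadjusted p under 0.05. No slide held both lines, and with slide as a random block (correlation 0.242) 35 genes passed.

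Guard cell and ABA-related lists shifted up together in slac1. The ABA-induced list had a median log2 change of 0.46 with 31 of 37 members above 0 (camera adjusted p = 7.44e-11; adjusted p = 0.167 with an estimated correlation). Past the threshold were 2 members, MYB74 and the dehydrin RAB18 (1.36, SE 0.18), and 6 adjusted over the list alone. The list means were -0.33, 0.01 and 0.14 in slac1 and -0.68, -0.52 and -0.48 in gl1-1. The guard cell identity list had a median of 0.47 with 12 of 15 members above 0 (camera adjusted p = 2.74e-08; adjusted p = 0.167 with an estimated correlation). Higher members were the myrosinase TGG1 (0.82, SE 0.07), the kinase MPK12 (0.98, SE 0.13) and ALMT12 (1.17, SE 0.16), and adjusted over the list alone 8 were higher and SLAC1 was lower. The ion transport list had a median of 0.25 (18 of 29 above 0, camera adjusted p = 9.29e-07; adjusted p = 0.167 with an estimated correlation). Its members past the threshold were SLAC1, the proton pump AHA5 (0.92), ALMT12 and the vacuolar antiporter NHX1 (0.89), and adjusted over the list alone 11 were higher and 1 lower. The identity and ion transport lists share several loci, among them SLAC1 and ALMT12, so their shifts are not independent.

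Other lists moved with them in slac1. The starch and malate list had a median of 0.25 with 15 of 18 members above 0 (camera adjusted p = 1.88e-06; adjusted p = 0.167 with an estimated correlation), SUS3 rising by 1.21 and 3 members passing adjusted over the list alone. Stomatal lineage genes had a median of 0.38 with 13 of 14 above 0 (camera adjusted p = 3.2e-06; adjusted p = 0.167 with an estimated correlation), 0 past limma's threshold over all genes, 5 adjusted over the list alone and 5 at an unadjusted p under 0.05. The receptor TMM, for example, had a log2 change of 0.80 (SE 0.19, limma adjusted p = 0.132). Epidermis and cuticle genes had a median of 0.18 (camera adjusted p = 2.54e-06; adjusted p = 0.185 with an estimated correlation), with CER1 and CER2 (0.76) higher and 4 members adjusted over the list alone. Flavonoid genes had a median of 0.15 (camera adjusted p = 0.000903; adjusted p = 0.357 with an estimated correlation), with flavonol synthase FLS1 up by 1.55 and 4 adjusted over the list alone, and their median was -0.03 without slac1 replicate 3 (adjusted p = 0.0153, still tested as up).

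Further lists passed in slac1. ABA receptors and kinases were called up with a median of 0.19 and a mean of -0.02 (camera adjusted p = 0.00305; adjusted p = 0.211 with an estimated correlation), with 6 higher and 2 lower adjusted over the list alone. ABA synthesis genes had a median of 0.04 (adjusted p = 0.00947; adjusted p = 0.185 with an estimated correlation; 0.0573 with quantile normalisation and 0.13 without slac1 replicate 2), with the transporter ABCG22 up by 0.78. The clock list had a median of 0.10 (adjusted p = 0.00947; adjusted p = 0.261 with an estimated correlation), and missed the threshold with the authors' values (median 0.20, adjusted p = 0.0922) and without slac1 replicate 2 (0.04, 0.138) or gl1-1 replicate 2 (0.09, 0.06). The list of CO2, calcium and light signalling was called up with a median of -0.05 and a mean of 0.16 (adjusted p = 0.0308; adjusted p = 0.185 with an estimated correlation), BLUS1 rising by 1.42 and MPK12 by 0.98. That call was lost under 3 of the 4 other scalings (adjusted p = 0.103 with normexp, 0.169 with quantile normalisation, 0.0516 with the authors' values) and without slac1 replicate 1 (0.0633) or gl1-1 replicates 2 (0.06) and 3 (0.0674).

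Glucosinolate genes shifted down in slac1 (median -0.34, 2 of 26 above 0, camera adjusted p = 0.000655; adjusted p = 0.363 with an estimated correlation), with 0 past limma's threshold and 5 lower at an unadjusted p under 0.05. The call was lost without slac1 replicate 3 (median -0.21, adjusted p = 0.552) and without gl1-1 replicate 3 (-0.23, 0.0833). Photosynthesis genes were called down (median -0.17, adjusted p = 0.0334; adjusted p = 0.724 with an estimated correlation), but the direction turned with normexp (0.33) and with the authors' values (0.27), and the median was -0.02 without slac1 replicate 2. The call was also lost with median centring (adjusted p = 0.054) and without gl1-1 replicate 1 (adjusted p = 0.208) or gl1-1 replicate 2 (0.06). Trichome (median -0.04, adjusted p = 0.244), vasculature (0.07, 0.358), jasmonate (-0.02, 0.9), salicylate (-0.13, 0.9), touch (-0.18, 0.9) and heat shock lists (-0.29, 0.126) did not pass.

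**Figure D2:**
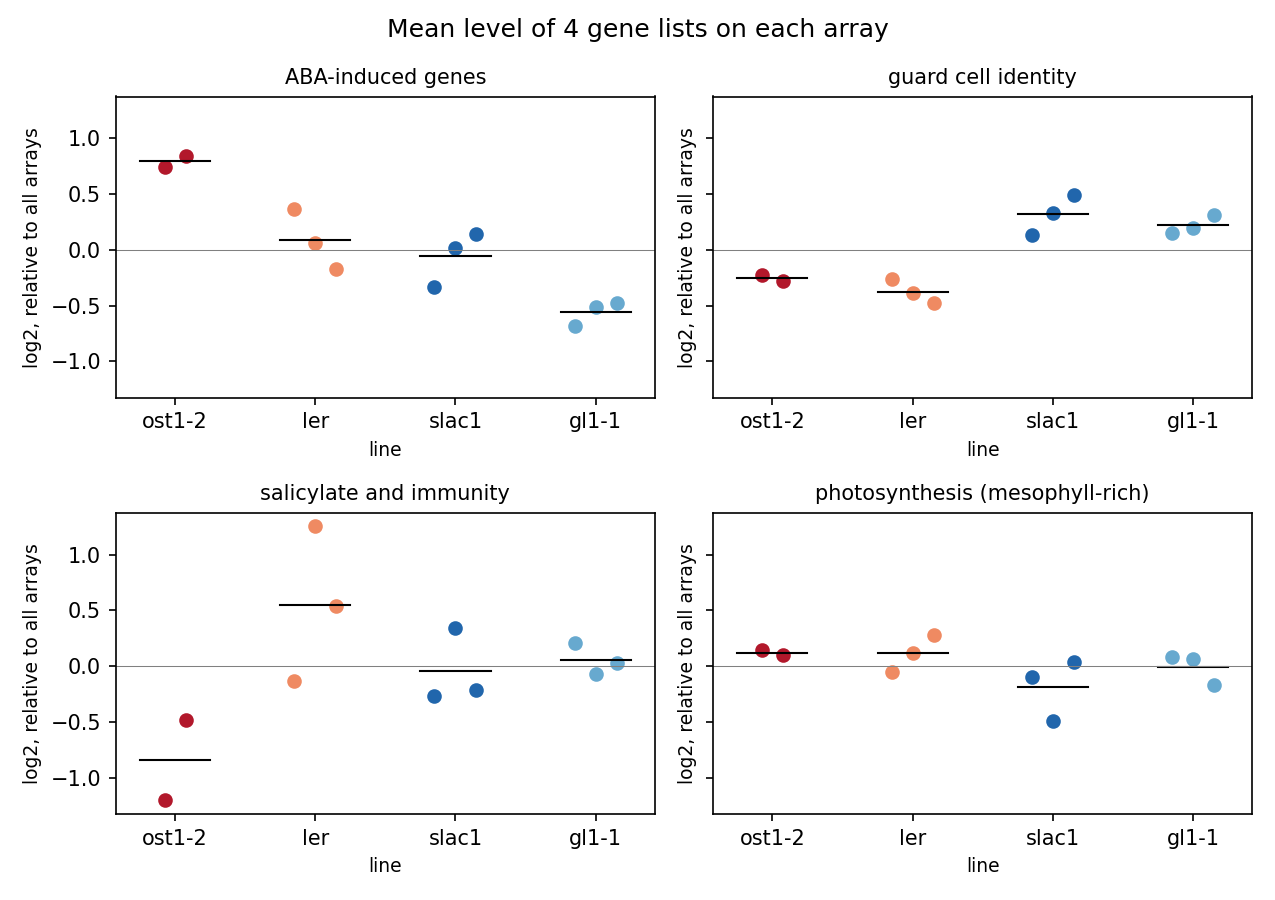
Mean level of the genes of 4 lists on each array, as log2 relative to the mean over all arrays, by line. Points are arrays and black bars group means. ABA-induced genes lie higher in ost1-2 (0.75 and 0.84) than in ler, and the salicylate list lies lowest in ost1-2 (-1.21 and -0.48). For photosynthesis genes, the direction in slac1 turned from a median of -0.17 to 0.33 with normexp and 0.27 with the authors' values.

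A set of genes was higher in both mutants. It held 36 genes, against 0.379 for independent lists of 85 and 107 genes among 24027. The lists were not independent, since both comparisons drew each gene's spread from 1 fit and slide 1 held an array of each mutant and no control. Leaving out slide 1 left 1 ost1-2 array, too few for a count of genes passing to decide anything. Without slide 1, 0 genes passed in both by limma, while the medians of the 36, which were picked with the remaining arrays as well, went from 1.15 to 1.08 in ost1-2 and from 1.23 to 1.21 in slac1. Their log2 changes ranged from 0.55 to 3.33 in ost1-2 and from 0.51 to 2.43 in slac1, and none of the 36 passed the test of the difference between the mutants. Among them were LOG5, MYB74, CER1, BLUS1, SUS3 and RAB18 (1.32 in ost1-2, 1.36 in slac1), and 25 changed at least 2-fold in both. By limma, 0 genes were lower in both and 0 changed in opposite directions. At an unadjusted p under 0.05 in both, 334 genes were higher (77.9 for independent lists), 219 lower (159), 104 higher in ost1-2 and lower in slac1 (82.0) and 105 the reverse (151). The guard cell identity markers had median changes of 0.22 and 0.47 in the same comparisons.

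**Figure D3:**
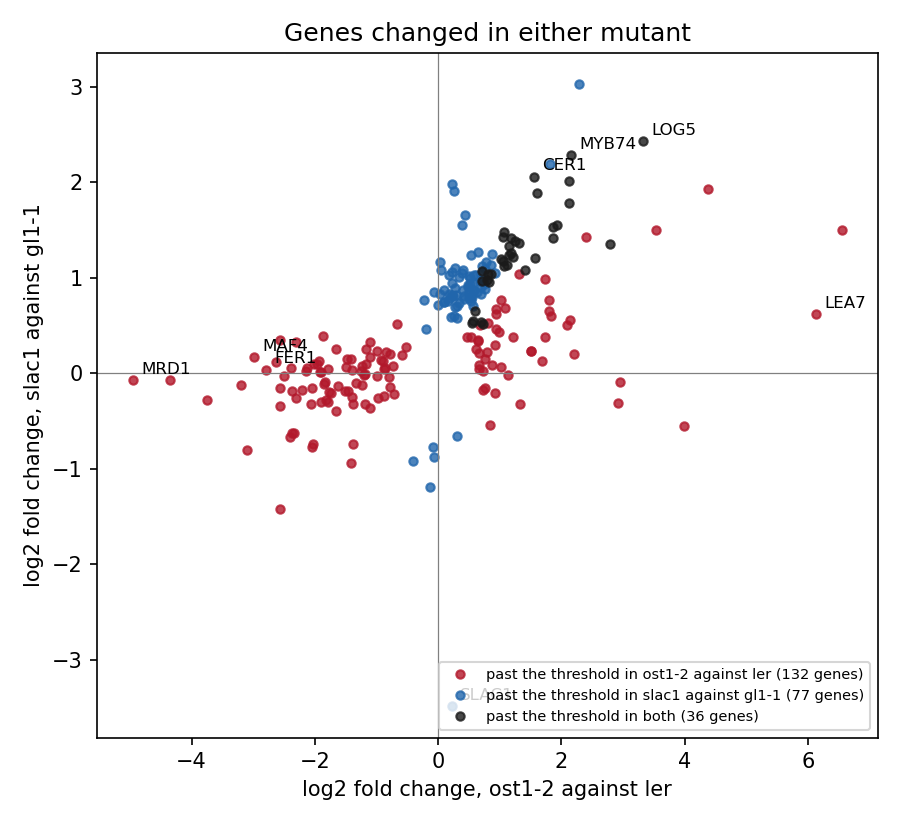
Log2 fold changes of the 245 genes past the threshold in either mutant, ost1-2 against ler on the horizontal axis and slac1 against gl1-1 on the vertical axis. Each point is a gene, coloured by the comparison in which it passed. The 36 genes past the threshold in both lie above 0 on both axes.

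Across all genes, which are not independent replicates, the fold changes of the 2 mutants correlated with r = 0.575 and rho = 0.349. The correlation depended on the scaling. It was r = 0.575 with median centring, 0.237 with quantile normalisation, 0.149 with normexp and quantile normalisation, and 0.185 with the authors' values. With probes above background on all 11 arrays r was 0.186, and without a filter on dim probes 0.551. Over the brighter genes (those above the median of mean signal) r was 0.0906 and rho -0.05, and over the dimmer genes r was 0.547 and rho 0.495. The number of shared genes fell to 3 and 4 without ost1-2 replicates 1 and 2, to 17, 8 and 13 without ler replicates 1 to 3, to 16 and 7 without slac1 replicates 1 and 2, and to 3, 2 and 22 without gl1-1 replicates 1 to 3. It rose to 274 without slac1 replicate 3. With slide as a block in both comparisons 0 genes passed in both. In that setting only 2 genes, MRD1 and FER1, passed in ost1-2, both lower, and 34 of 35 were higher in slac1. A count of 0 was thus nearly fixed in advance and says little about the shared genes.

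The changes differed between the mutants for 17 genes, 12 of them more negative in ost1-2. LEA7 rose by 6.14 in ost1-2 and had a log2 change of 0.62 in slac1 (difference 5.52, SE 0.67, limma adjusted p = 0.0363). MRD1 fell by 4.96 in ost1-2 and had a log2 change of -0.07 in slac1 (difference -4.89, SE 0.34, adjusted p = 0.00481), and FER1 differed by -2.83 (SE 0.27, adjusted p = 0.021). SLAC1 itself differed by 3.71, and CYP77A6 by -1.18. The call of a difference was lost in 17 of 25 other settings for LEA7, 11 of 26 for SLAC1 and 17 of 26 for CYP77A6. For FER1 it was lost in 9 of 26, and for MRD1 in 1 of 26. The salicylate list differed with a median of -0.83 (0 of 21 above 0, camera adjusted p = 3.85e-05; adjusted p = 0.852 with an estimated correlation), with 0 past limma's threshold and 5 lower at an unadjusted p under 0.05. Glucosinolate genes differed by 0.34 (adjusted p = 0.00326; adjusted p = 0.852 with an estimated correlation), a call lost with array weights (0.136) and without slac1 replicate 3 (0.213) or gl1-1 replicate 3 (0.0837). Stomatal lineage genes differed by -0.42 (adjusted p = 0.01; adjusted p = 0.852 with an estimated correlation), a call lost with the mean over probes (0.0585). The salicylate call was lost without slide 1 (0.0709). The guard cell identity list differed by -0.23 (adjusted p = 0.0682).

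The 17 genes were 29.4% higher, against 46.6% of 58 with normexp, 20.0% of 5 with quantile normalisation, 12.5% of 8 with median centring and 63.2% of 19 with the authors' values. There were 2944 genes at an unadjusted p under 0.05. The count was 6 and 4 without ost1-2 replicates 1 and 2, 7, 4 and 2 without ler replicates 1 to 3, 2 and 10 without slac1 replicates 1 and 2, and 2, 3 and 2 without gl1-1 replicates 1 to 3.

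The control lines differed from each other far more than either mutant from its control. Their comparison shares the gl1-1 arrays with slac1 against gl1-1, where these arrays enter with the opposite sign. Low gl1-1 values thus give a fall here and a rise in slac1. The ABA-induced, stomatal lineage, epidermis and starch lists were called down here and up in slac1, so these calls are not independent. The trichome and touch lists, also called down here, did not pass in slac1. The labels do not give the accession in which the gl1-1 line stands, so a difference between accessions cannot be told apart from an effect of gl1-1. Of 26 glucosinolate genes, 11 were higher in gl1-1 and 3 lower. AOP2 was 19.4-fold higher (log2 change 4.27, SE 0.20, limma adjusted p = 1.95e-06) and the regulator MYB29 was 8.56-fold higher (SE 0.22, adjusted p = 2.06e-05). AOP3 fell by 9.91, measured in 2 of 3 gl1-1 arrays, and ESP, which directs glucosinolate breakdown, by 4.73, while GSOX3 rose by 2.84. The list did not shift one way (median 0.27, camera adjusted p = 0.244). Several genes with large rises in gl1-1 were not well above background in ler. These were AT1G66100, at least 901-fold for its brighter probe (log2 change 6.19 for the other), AT5G40500, at least 308-fold, AT1G29790, at least 245-fold, and AT1G65280, at least 156-fold. AT2G25510 rose by 11.3, SADHU1-1 by 10.3, AT4G34881 by 10.04 (measured in 1 of 3 ler arrays) and AT4G04692 by 9.63. Lower in gl1-1 were AT4G04402, at least 113-fold, AT3G44070, at least 85.9-fold, and AT5G15360, at least 75.7-fold, with AT1G24370 (measured in 1 of 3 gl1-1 arrays), SADHU9-1, AT4G32230 (in 2 of 3) and AT1G24388 at -7.34, -6.66, -6.30 and -5.88.

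Of 14 lineage genes 10 fell, with TMM at -2.24 (SE 0.19), BASL at -2.45, ERL1 at -1.94 and SCRM at -1.28 (list median -1.49, camera adjusted p = 6.25e-06; adjusted p = 0.629 with an estimated correlation; 11 lower adjusted over the list alone). Of 14 trichome genes 6 fell, among them CPC at -2.83, MYB23 at -1.55, GL2 at -4.58 (measured in 1 gl1-1 array) and HDG2 at -0.93, whose probes disagreed in sign (list median -0.68, camera adjusted p = 0.00172; adjusted p = 0.629 with an estimated correlation; 7 lower adjusted over the list alone). Over the brighter genes alone the trichome median was 0.04 (adjusted p = 0.315). Of 22 epidermis genes 1 was higher and 9 lower, with CER1 at -3.47, PDF1 at -2.61 (between -2.90 and -0.28 over its 5 probes), CYP77A6 at -1.27 and HTH at -0.97 (median -0.26, camera adjusted p = 0.00105; adjusted p = 0.629 with an estimated correlation).

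Of 20 touch and rapid stress genes 13 fell, with ERF6 at -2.27 (-0.49 for its other probe), CBF3 at -2.95 and ZAT12 at -1.39 (median -1.43, camera adjusted p = 1.54e-05; adjusted p = 0.629 with an estimated correlation). ABA-induced genes had 15 members lower and 1 higher, with LEA7 at -4.57, TSPO at -4.75 and the ABA synthesis gene NCED3 at -1.62 (median -0.46, camera adjusted p = 7.57e-05; adjusted p = 0.629 with an estimated correlation). Starch and malate genes had a median of -0.35 (adjusted p = 0.0374; adjusted p = 0.629 with an estimated correlation), a call lost with quantile normalisation (0.124), with the authors' values (0.102) and without ler replicate 1 (0.1). The defensin PDF1.2A rose by 9.08 and its regulator ORA59 by 3.36, though the jasmonate list did not pass (median -0.28, adjusted p = 0.199). The guard cell identity list did not pass (median 0.05, mean 0.60, adjusted p = 0.505), with the myrosinase TGG2 up by 6.56, measured in 2 of 3 ler arrays, and the potassium channel genes GORK and KAT2 up by 0.87 and 0.90. Clock genes had 5 members higher and 9 lower, with PRR3 at -2.70 and PRR7 at -1.15 (-0.09 for its other probe; list median -0.16, camera adjusted p = 0.16), and flavonoid genes had 3 higher and 1 lower, with UGT78D1 at 2.59 (median 0.74, adjusted p = 0.259). The heat shock list lay higher without passing (median 0.52, 10 of 12 above 0, adjusted p = 0.259). The salicylate list missed the threshold (median -0.56, adjusted p = 0.0556), with WRKY70 at -1.66 and WRKY54 at -2.31.

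In all, 7134 genes passed, 3998 higher and 3136 lower (56.0% higher, against 45.6% with normexp, 45.0% with the authors' values, 47.5% with quantile normalisation and 46.6% with median centring). No slide or scan day held both lines, and with slide as a random block 5012 genes passed. Of 2203 such genes with several tested probes, the probes of 465 disagreed in sign. Among them were HDG2 and LHCB2.1 (-1.42 for its brightest probe, 10.5 for the other). In ost1-2 against ler the probes of 4 of 58 such genes disagreed, and in slac1 against gl1-1 those of 5 of 38. A change read from 1 probe in gl1-1 against ler therefore need not hold for the gene's other probes.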

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

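The later tests of slide 1 and the tests of guard cell share, ABA-induced genes, slac1 replicate 3 and neighbouring genes were chosen only after the results were seen. The change differed between the mutants for MRD1 (-4.89), AT4G06536 (-4.29, with -0.24 for 1 of its other probes), MAF4 (-3.15), FER1 (-2.83), AT2G32340 (-2.63), AT3G59260 (-2.44), AT1G10160 (-2.19), HEI10 (-1.90), AT2G31550 (-1.59), AT1G10610 (-1.43), NAC088 (-1.28) and CYP77A6 (-1.18), all more negative in ost1-2. It was more positive in ost1-2 for AGD9 (0.96), UBP21 (1.15), AT5G26220 (1.58), SLAC1 (3.71) and LEA7 (5.52). AGD9 lost this call in 19 of 26 other settings, UBP21 in 14 of 26 and AT5G26220 in 10 of 26. Among lists, stomatal lineage differed by -0.42, salicylate and immunity by -0.83 and glucosinolate by 0.34, all lost with an estimated correlation (camera adjusted p = 0.852 for each).

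Of the 36 genes higher in both mutants, the part played by slide 1, which held an array of each mutant, was tested first. The 100 brighter genes rising most in ost1-2 without slide 1 had a median slac1 change of 0.00841 (50 above 0), which is what slide 1 as the cause predicted, but the same choice with all arrays gave 0.08 (54 above 0), so this test does not separate the cases. Medians of the shared genes without slide 1 (1.08 and 1.21, against 1.15 and 1.23 with it) decide nothing. The shared genes were picked with those same arrays. Ranking brighter genes by moderated t in ost1-2 without slide 1 gave a median slac1 change of 0.47, with 82 of 100 above 0. Over all brighter genes the median was -0.02, with 46.0% above 0. Slide 1 enters neither side of this ranking, so it did not produce that rise. The ranking rests on 1 ost1-2 array, and ranking by size gave no such rise, so the part played by slide 1 stays open. A higher share of guard cells stays open in both mutants, where 10 and 12 of 14 markers lay above 0: the shared genes exceeded the markers by 0.95 in ost1-2 and 0.70 in slac1, but were picked for rising. ABA-induced genes numbered 2 among the shared genes against 0.0554 expected (Fisher's exact p = 0.00141), a test on 2 genes already seen there, so a common ABA-related state stays open as well.

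Replicate 3 of slac1 lay near gl1-1 on the second principal component. A gl1-1 sample under a slac1 label was argued against by SLAC1, which lay 3.59 log2 units below the lowest gl1-1 array (-3.59), and the fall without this array was -3.35. Over the brighter genes the array correlated more with slac1 (0.992) than with gl1-1 (0.981), a difference of 0.0107, and over the dimmer genes less (0.865 against 0.955). Signal at the dim end of the range could therefore set it apart, and what produced that signal stays open. Among the 10 ways to split these 6 arrays, 2 gave as many genes as the real 113 or more, counting the real one, with 2765 for slac1 replicates 1 and 2 with gl1-1 replicate 3. For gl1-1 and ler, 1 of 10 did, the real one with 7134 and 0 in the rest, and 10 splits are too few for a share under 0.05.

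Genes changed in ost1-2 included 8 neighbouring pairs, against a mean of 1.19 in 10000 random sets (permutation p = 2e-04). Neighbours were genes next to each other among those tested on a chromosome. The pairs overlapped, as MRD1 paired with both MSL4 and HEI10, and AGD9 with both UBP21 and MYC3. Random sets were drawn evenly over genes, without regard to clusters of related genes, so only even random spacing is argued against. In slac1 there were 2 pairs against 0.528 (permutation p = 0.096), and in the difference 2 against 0.01 (permutation p = 2e-04). Pairs included CRK7 with CRK8 (-2.49 and -2.05) and UBP21 with AGD9 (1.14 and 1.02), while MSL4 (1.41) and MRD1 (-4.96) changed in opposite directions. A stretch of the genome that differs in the ost1-2 line could act on both genes of a pair, and in 2 pairs, MRD1 with HEI10 and UBP21 with AGD9, both differed between the mutants. Shared local regulation would give the same pattern, so this stays open.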

How the results depend on the processing

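The groups held 2 or 3 arrays, and line and slide were largely the same thing in this design. The gene counts of the mutant comparisons moved with most settings, that of gl1-1 against ler with 2, and the cause was not tested. Genes changed in ost1-2 against ler numbered 168, in slac1 against gl1-1 113, in the difference 17, in gl1-1 against ler 7134 and in both mutants 36.

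With normexp and quantile normalisation these became 260, 503, 58 and, in both mutants, 85. Quantile normalisation gave 179 in slac1 and 5 in the difference, median centring 8 in the difference, and the authors' values 762 in slac1 and 68 in both. Without a filter on dim probes there were 74 in slac1 and 22 in both, and with probes above background on all arrays 327, 267 and 68 in both. A 2-fold threshold left 56 in slac1 and 2594 in gl1-1 against ler. With only the 2 groups compared there were 497 in ost1-2 (78 higher, 419 lower), 0 in slac1 (1992 at an unadjusted p under 0.05 by limma) and 0 in both. Trended and robust eBayes gave 388, 346, 50 and 79 in both. Array weights gave 2045, 6005, 815, 11807 and 573 in both, with most of the genes lower in ost1-2 (1365) and in slac1 (4731).

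Replicate number as a block gave 26 genes in ost1-2, and by limma 0 in slac1 (2242 at an unadjusted p under 0.05), 0 in the difference (2181) and 0 in both. Between arrays with the same number, deviations from the group mean correlated at -0.07 and 0.05 for ost1-2 with ler. For slac1 with gl1-1 the values were -0.12, -0.62 and -0.64. These values show no sign of pairing by number. They cannot exclude it, since deviations within groups of 2 or 3 arrays depend on each other. Slide as a block gave 2 genes in ost1-2, 35 in slac1 and 0 in both.

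Leaving out single arrays gave 26 to 568 genes in ost1-2, 5 to 2862 in slac1, 2 to 22 in the difference and 2 to 274 in both, the highest each time without slac1 replicate 3.

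The photosynthesis list turned in slac1 to 0.33 with normexp (camera adjusted p = 5.6e-06) and to 0.27 with the authors' values (0.00021). Its difference between the mutants turned to -0.22 (0.014) and -0.22 (0.0366). Without slac1 replicate 2 the photosynthesis list in slac1 had a median of -0.0234 and was not called in either direction (camera adjusted p = 0.991). Without slide 1 its median was -0.0234 as well. Over single omissions its median ran from -0.28 to -0.0234. The touch list in slac1 was 0.13 with array weights. In gl1-1 against ler, the mean over probes gave 4.53 for LHCB2.1 and 0.16 for HDG2. With a correlation estimated for each list, 0 list shifts passed by camera, against 20 at the preset correlation in the mutant comparisons and their difference. The 6 list calls in gl1-1 against ler were lost as well.

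Alternatives chosen after seeing the data were fits without slide 1 (8 in ost1-2, 1 in slac1, 4 in the difference, 0 in both), scan day as a block (28, 43 and 3 in both) and the brighter genes (347 in slac1, 44 in the difference, 66 in both).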

Other observations

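Several regulators and transporters beyond those set by the naming rule, chosen after the values were seen, rose in both mutants. All are among the 36 genes higher in both, and the limits given for that set hold for them too. The heat stress factor gene HSFA6A rose by 2.79 in ost1-2 and 1.35 in slac1, and MYB102, a factor of osmotic and wound responses, by 1.60 and 1.89. The cell wall enzyme gene GAUT12 rose by 2.12 and 1.78, the peptide transporter PTR3 by 1.87 and 1.53, and the mechanosensitive channel relative MSL4 by 1.41 and 1.08.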
